A study of Leishmania major with 3 samples.

How the data were processed

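The study measured RNA 3′ ends along the ribosomal RNAs of Leishmania major, a kinetoplastid parasite, in the promastigote stage (the form that grows in culture). Per the labels' protocols, the cells of strain Friedlin were cultured at 27 °C in medium with 10% serum, and 1 µg of total RNA entered each RibOxi-seq library. In this assay the nuclease Benzonase fragments the RNA, and rounds of oxidation, β-elimination and dephosphorylation remove 3′-terminal nucleotides that carry a free 2′ hydroxyl. A 2′-O-methylated nucleotide at a 3′ end resists oxidation and keeps an end to which a linker can be joined, so its position collects read ends. The series holds 3 libraries of a single group, titled LM1, LM4 and LM5. Nothing in the labels says whether they came from separate cultures, so the p-values of the edgeR test measure the spread between these libraries only, which may be technical. The Fisher, permutation and sign tests are over positions or windows. The labels name no library prepared without oxidation.

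The authors deposited a table of whole-number counts per rRNA position and library. Its header names the rRNA, the position and the libraries, and the values are raw counts: they were not scaled to a common total. The submitters' processing notes name cutadapt 2.10, STAR 2.7.5c, SAMtools, UMI-tools 1.01 and bedtools 2.29.2, without giving their role or order. The reference sequence, the filters and whether duplicate molecules were removed are not given in the sources used here. The table lists 6087 positions on 8 sequences named SSU, LSU5, LSU3, 5.8S, SR1, SR2, SR4 and SR6. No position before 20 is listed. The 40 positions missing between the first and last listed position of a sequence were taken as 0.

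The authors also deposited a score per position, the mean over the libraries, for the 5556 listed positions of SSU, LSU5, LSU3 and 5.8S. Its formula is not given in the sources used here. The deposited score was equal, to a relative tolerance of 0.0001, at all 5556 positions to a ratio rebuilt from the counts: the count at a position over the mean count of the listed position before and after it plus 1, taken per library and then averaged. At the ends of a sequence the only neighbour was used. The score is thus a ratio, not a fraction with an upper limit of 1, and the rebuilt score per library gave its spread.

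The libraries totalled 222349 (LM1), 213915 (LM4) and 201166 (LM5) counts, with a median of 16, 16 and 15 per listed position. A count of 16 has an exact 95% Poisson interval of 9.15 to 26.0 and a count of 1000 one of 939 to 1064. These intervals cover counting error only, since read counts may hold copies of one molecule. For a count of 0 a one-sided 95% limit of 3 counts was taken. The libraries were compared before use: a chi-square test over positions with at least 20 counts per pair found that each pair differed by more than sampling noise, so no pair was treated as a library given more than once. This does not show that they came from separate cultures.

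The test, its threshold and its filters, the rule for named sites and the alternatives were chosen before the data were examined, except where stated. Each position was compared with the 6 positions on each side of it in the same rRNA by the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmTreat). The model held a library term and a term for position against flank. Library totals and the number of summed positions entered as offsets. The null hypothesis was a difference of at most 4-fold, and positions higher than their flanks at a Benjamini-Hochberg adjusted p under 0.05 were called. Of the listed span, 96 positions lacked a full flank and 154 had a mean under 10 counts (position plus flank mean). The other 5877 were tested. The standard error of a log2 fold, a definition added later, is that implied by the quasi-likelihood F statistic. Neighbouring positions share flanks, so their tests are not independent. Fold values per library used a pseudocount of 1. On simulated counts with a smooth background and 50 planted sites at each of 4 fold sizes (5712 positions tested), the test called 44% of the 6-fold, 78% of the 10-fold, 90% of the 20-fold and 100% of the 40-fold sites, and 0 unplanted positions. The simulated background varied less between neighbouring positions than the real counts. The 0 therefore does not measure false calls in the real counts, and recovery there may differ. Planted 40-fold sites (log2 5.32) were estimated at a median log2 fold of 5.09.

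Sites named in the text followed a fixed rule: of the calls with more than 4-fold in each library, the 10 with the largest fold in SSU and the 15 with the largest in the large subunit rRNAs (5.8S included), plus the positions with the authors' 5 highest scores, which were already among them. Because the score has no upper bound, the highest-scoring positions were taken in the number of calls on the same rRNAs. Calls per rRNA were compared by Fisher's exact test (100000 simulated tables) and neighbouring calls by a two-sided permutation test (100000 draws). The alternatives were other flank widths, fold thresholds, count filters, pseudocounts and tools (DESeq2 1.42.0, limma 3.58.1), a fit without the library term, and each library left out in turn. The 16-fold threshold was added after the data were seen. The planned comparisons of bases at called positions and of conserved sequence motifs were not run, because no rRNA sequence was used here. Positions are those of the authors' rRNA sequences, counted from 1. They are not genome coordinates, and the genomic copy of each rRNA is not distinguished. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining calculations.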

Results

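The data were counts of RNA 3′ ends at each position of the L. major ribosomal RNAs in 3 RibOxi-seq libraries of promastigote total RNA. The question the design poses is which rRNA nucleotides carry a 2′-O-methyl group. This modification is placed on rRNA largely by proteins guided by box C/D small nucleolar RNAs. Because the labels name no library without oxidation, whether a called position carries this group was not tested. The calls below are positions with counts above their flanks. The files divide the rRNA into the small subunit rRNA (SSU), the pieces of the large subunit rRNA called LSU5 and LSU3, 5.8S, and the small rRNAs SR1, SR2, SR4 and SR6. Large subunit rRNA in several separate pieces is a feature of kinetoplastids. Library totals lay between 201166 counts in LM5 and 222349 in LM1.

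SSU held 34.1% ± 0.28 of the counts, LSU5 28.6% ± 2.1 and LSU3 25.2% ± 1.5 (SD, n = 3). These shares were close to the shares of positions, 35.6%, 28.8% and 24.5%. 5.8S held 3.23% ± 0.098 of the counts on 2.45% of the positions. The small rRNAs held between 1.10% ± 0.091 (SR6) and 3.36% ± 0.27 (SR1). The SSU share differed little between libraries. The LSU5 share was 30.2% in LM1, 29.4% in LM4 and 26.3% in LM5, and the LSU3 share ran the other way, at 24.0%, 24.6% and 26.8%. SR1, SR2, SR4 and SR6 each had their largest share in LM5.

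**Figure D1:**
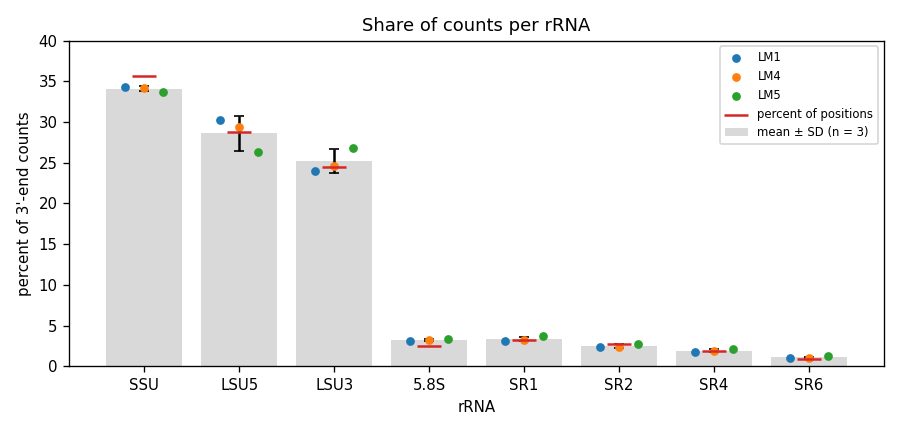
Percent of all 3′-end counts on each rRNA (bars, mean ± SD over 3 libraries; points, the libraries; red lines, percent of positions). LM5 has the lowest LSU5 share (26.3%) and the highest LSU3 share (26.8%).

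Across the 3920 positions with a mean of at least 10 counts, log2 counts correlated between LM1 and LM4 with Pearson's r of 0.936 and Spearman's rho of 0.904. The rho was 0.886 between LM1 and LM5 and 0.878 between LM4 and LM5. These correlations are across positions, which are not independent replicates. The chi-square per degree of freedom over positions was 1.29 for LM1 and LM4, 1.82 for LM1 and LM5 and 1.99 for LM4 and LM5, so LM5 stood farther from the others than they did from each other. Taken singly, LM1, LM4 and LM5 placed 264, 252 and 271 positions more than 4-fold above their flanks, and 218 of these positions were shared by all libraries.

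Of 5877 tested positions, 220 (3.74%) exceeded their flanks by more than 4-fold (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted). They held 30.8% ± 0.48 of all counts (SD, n = 3). Among the calls, 211 were above 4-fold in each library. The median log2 fold of the calls was 3.13, and they ran from 2.25 to 8.41. In the other direction, 904 positions lay more than 4-fold below their flanks; a single high position raises the flank mean of the 12 positions around it. The number of calls was set mainly by the fold threshold: 586 at 2-fold, 103 at 8-fold and 58 at 16-fold, the last chosen after the data were seen.

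**Figure D2:**
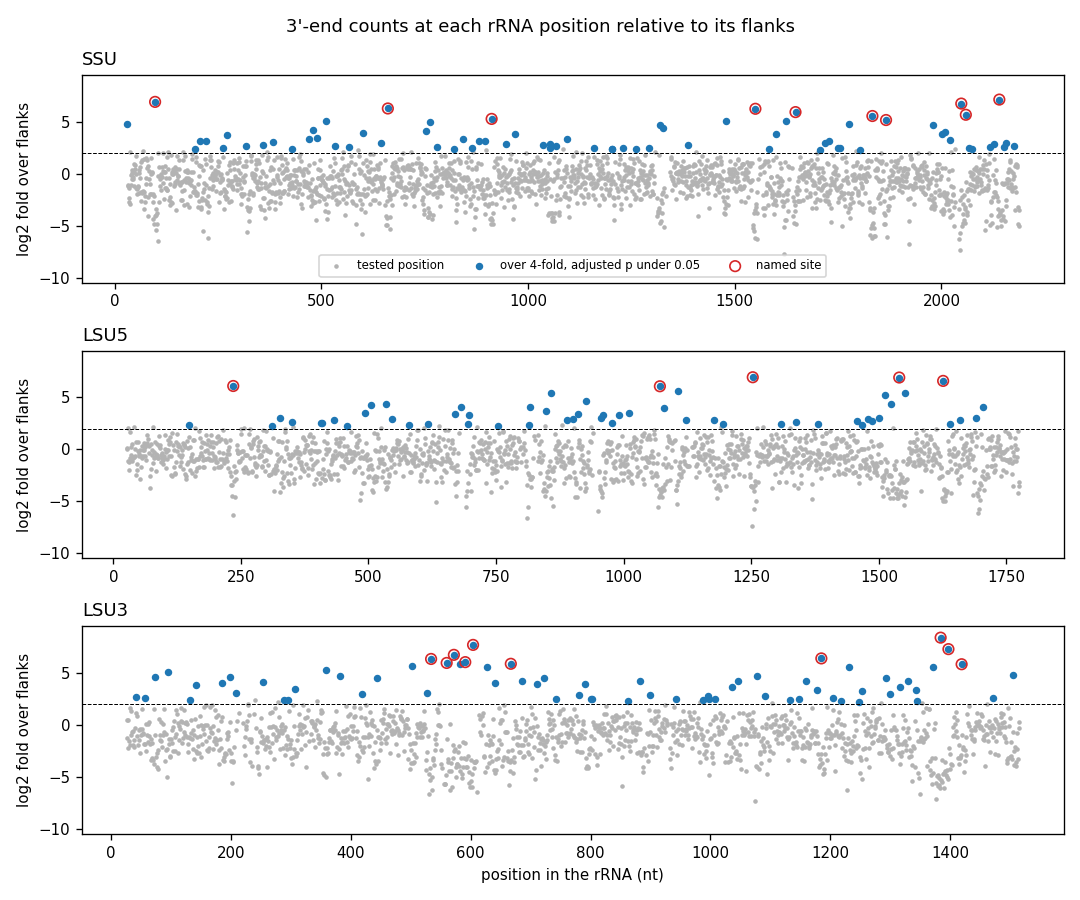
Log2 fold of the 3′-end count at each tested position over its flanks (y axis) along SSU, LSU5 and LSU3 (x axis, nt); blue points were called, red circles are the named sites and the dashed line is 4-fold. Named sites reach a log2 fold of 8.41 at LSU3 1384; 16 tested positions with 0 counts in every library lie below the axis.

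In SSU, 74 of 2109 tested positions were called. With flanks of 6 positions the largest excess was at position 2140, with 484 ± 74.9 counts (SD, n = 3) against a flank mean of 3.47 (log2 fold 7.12, SE 0.17). Its log2 fold per library ran from 6.096 to 7.195 (SD 0.598), the widest spread of the 25 named sites. Position 98 followed with 623 ± 61.2 counts (log2 fold 6.89, SE 0.14) and position 2048 with 593 ± 109 counts (log2 fold 6.73, SE 0.14). The SSU positions 661, 1550, 1647, 2059, 1833, 912 and 1866 completed the 10 largest, with log2 folds of 6.26, 6.23, 5.91, 5.66, 5.54, 5.26 and 5.15. Their order changed with the flank: of these 10, SSU 1833 had the largest log2 fold with flanks of 2 positions (7.89) and with the flank median (7.72), and SSU 98 with flanks of 12 (6.24, against 5.61 at SSU 2140). SSU 98 was also above SSU 2140 with a pseudocount of 5 (5.94 against 5.85) and without LM4 (6.96 against 6.88). Their adjusted p in edgeR lay between 1.29e-22 for position 98 and 9.77e-20 for position 2059. Position 912 had the highest count of these (969 ± 79.2), but also the highest flank mean, 25.3. Position 1550 was the least even in its counts, with 306, 315 and 166 in LM1, LM4 and LM5 (coefficient of variation 31.8%). It was still above its flanks by a log2 fold of at least 5.24 in each library.

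In LSU5, 57 of 1708 tested positions were called, and in LSU3 70 of 1453. With flanks of 6 positions LSU3 1384 had the largest excess of the 5877 tested positions, with 1024 ± 61.6 counts, a 341-fold difference from its flanks (log2 fold 8.41, SE 0.16, edgeR adjusted p 2.92e-23). With flanks of 12 positions its log2 fold was 5.36, below most of the other named sites, led by LSU3 604 (7.90) and LSU3 1397 (7.12). LSU3 604 had 957 ± 39.2 counts (log2 fold 7.72, SE 0.15) and LSU3 1397 had 815 ± 33.3 (log2 fold 7.31, SE 0.15). LSU5 1253 carried more counts than LSU3 1384 in each of the 3 libraries, 1159 ± 128 on average, but over a higher flank of 9.44 (log2 fold 6.94, SE 0.14). LSU5 1540, 1626, 235 and 1071 had log2 folds of 6.91, 6.58, 6.09 and 6.07. The other LSU3 positions among the 15 largest were 572, 1185, 534, 591, 560, 667 and 1419, with log2 folds from 6.76 to 5.86. Of these 15, 10 were in LSU3 and 5 in LSU5. The log2 folds of LSU5 1253 and LSU5 1540 differed by less than their standard errors (0.14 and 0.15). Count variation at LSU5 235 (619, 618 and 361 counts in LM1, LM4 and LM5) was the widest of these large subunit sites, at 27.9%.

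**Figure D3:**
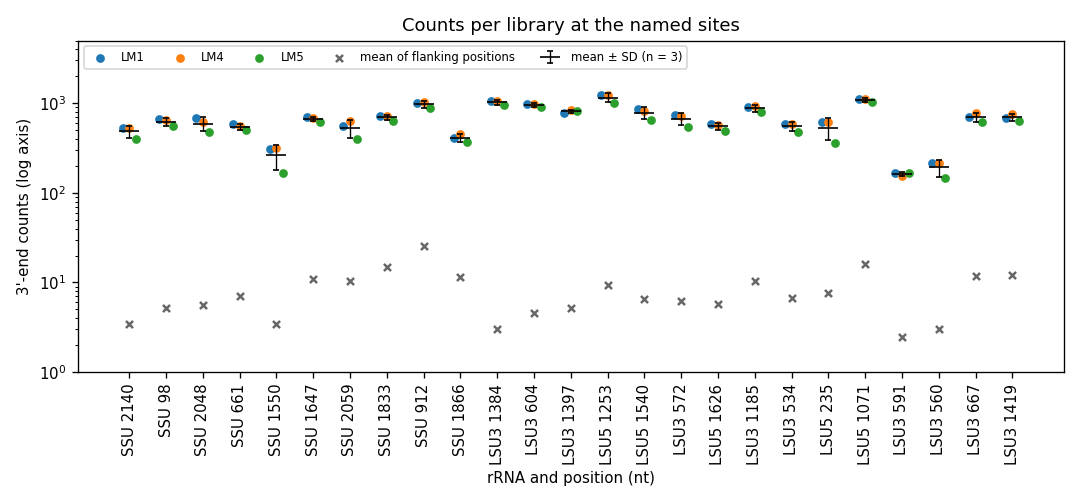
3′-end counts (log axis) at the 25 named sites in LM1, LM4 and LM5, with mean ± SD (n = 3) and the mean count of the flanking positions (crosses). The site counts lie between 145 in LM5 at LSU3 560 and 1234 in LM4 at LSU5 1253, all above the flank means of 2.44 to 25.3.

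5.8S rRNA, which pairs with the large subunit rRNA, had 4 called positions among 128 tested, named here after their values were seen because they are few. Position 43 had 799 ± 91.0 counts (log2 fold 5.54, SE 0.14), position 75 had 773 ± 78.0 (4.96, SE 0.13), position 162 had 608 ± 99.9 (5.79, SE 0.13) and position 124 had 803 ± 55.2 (4.03, SE 0.12). In the small rRNAs the log2 folds of the calls lay between 2.33 and 4.39. SR2 had 7, led by position 116 with 259 ± 16.5 counts and a log2 fold of 4.39. SR1 had 4, at positions 83, 135, 180 and 201, with log2 folds of 3.62, 2.74, 2.57 and 2.33. SR4 had 2, at positions 64 and 75 (3.17 and 2.44), and SR6 had 2, at positions 35 (2.85) and 44 (167 ± 17.5 counts). Of the calls in these small rRNAs, SR1 201 had the largest edgeR adjusted p, 2.83e-02.

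The share of tested positions called was highest in LSU3, at 4.82% (exact 95% binomial interval 3.78 to 6.05). It was 3.51% (2.77 to 4.39) in SSU, 3.34% (2.54 to 4.30) in LSU5, 3.12% in 5.8S, and between 1.94% (SR4) and 4.76% (SR6) in the small rRNAs. No difference in these shares over the 8 rRNAs was detected at the 4-fold threshold (Fisher's exact test with simulated tables, p = 0.303). LSU3 against all other rRNAs gave an odds ratio of 1.44 (two-sided Fisher's exact test, p = 0.0166, adjusted over 8 rRNAs 0.133). At 8-fold the shares differed (Fisher's exact test, p = 0.0157): LSU3 had 42 calls (2.89% of tested positions), SSU 30 (1.42%) and LSU5 24 (1.41%), 5.8S had 4 of 128 (3.12%), and SR4 and SR6 had 0 of 103 and 0 of 42. With flanks of 2 positions they differed as well (Fisher's exact test, p = 0.00424), with LSU3 at 5.82%.

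The counts beside called positions were low, in part by construction: a call must exceed flanks that include these neighbours, and only calls with no other call nearby were taken. At the 196 calls with no other call within 6 nt, the median log2 count over the local background (positions 4 to 6 nt away) was 3.63 ± 0.078 (SD over 3 libraries) at the site. At 1 nt upstream it was -0.32 ± 0.064, and at 1 nt downstream -0.0073 ± 0.072. At 3 nt the order was the other way, with -0.209 ± 0.087 upstream and -0.55 ± 0.046 downstream. In all, 3 pairs of directly adjacent positions were called, LSU3 1343 and 1344, SSU 1053 and 1054, and SSU 1203 and 1204, where random placement gave 8.11 (two-sided permutation test, p = 0.0705). Each of 2 adjacent high positions raises the flank mean of the other, which works against such pairs at every flank width, so random placement is not the value for unrelated sites in this test. Without LM1 there was 1 pair among 199 calls (permutation p = 0.0171), and without LM4 there were 5 among 219 (permutation p = 0.355). SSU 1053 and 1054 had 335 and 264 counts, and both SSU 1203 and SSU 1204 had a mean of 66.3.

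**Figure D4:**
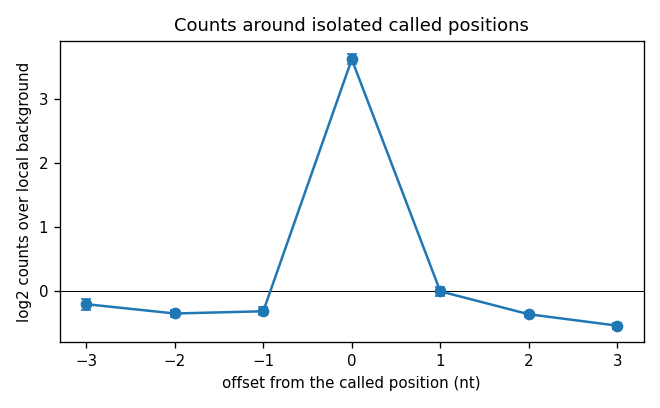
Median log2 count over local background (y axis) at offsets of -3 to 3 nt from 196 isolated called positions (x axis; negative is upstream), as mean ± SD over 3 libraries. The value is 3.63 at the site and 0 or below at each neighbour, partly because calls had to exceed flanks that include these neighbours.

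The authors' deposited score had a median of 0.779 over 5556 positions, and 40 positions scored 50 or more. Its 5 highest values were at LSU3 1384 (392), SSU 1833 (248), LSU5 1253 (228), LSU3 534 (217) and SSU 912 (197), all among the named sites. The score of LSU3 1384 rebuilt from the counts was 266 in LM1, 528 in LM4 and 381 in LM5 (SD 131, n = 3). The 2 neighbouring positions, which form its denominator, held only 6, 2 and 3 counts together in these libraries. In LM1 alone, SSU 1833 (290) and LSU5 1253 (274) scored above LSU3 1384. Over the 10 highest scores the median coefficient of variation was 26.9% for the score and 9.0% for the count at the same position.

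**Figure D5:**
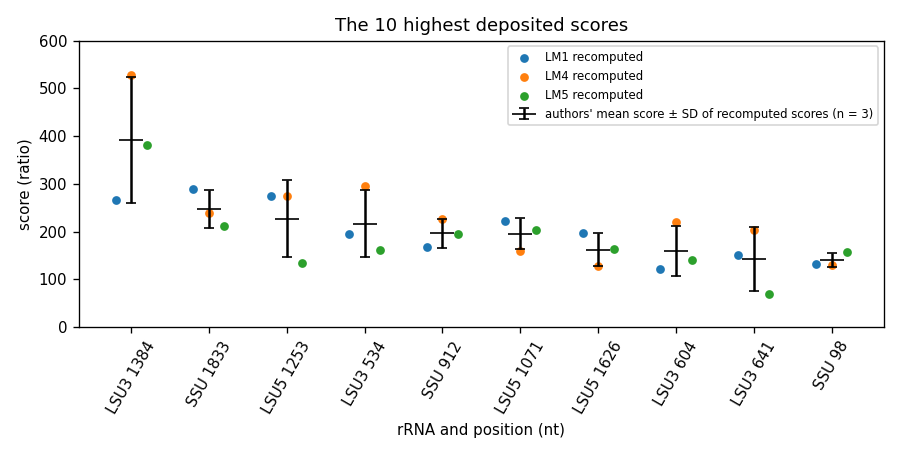
The authors' 10 highest deposited scores (black, with the SD of the scores rebuilt from the counts, n = 3) and the rebuilt score in each library (points), as a linear ratio. The score of LSU3 1384 spans 266 to 528, overlapping SSU 1833 at 213 to 290.

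Of the 205 highest deposited scores among positions in both tables, 139 (67.8%) were also called from the counts, against 7.81 expected by chance (two-sided Fisher's exact test, p = 1.70e-170). Score and call come from the same counts, so this is a description and not independent evidence. Among the 50 highest scores 46 were called. The highest-scoring positions that were not called were named after their values were seen. SSU 1829 scored 55.6 in the authors' deposited table, but its 148 counts exceeded a flank mean of 65.3, which includes SSU 1833, by a log2 fold of only 1.18. LSU5 1527 scored 50.2 at 80.7 counts (log2 fold 2.08, edgeR adjusted p 0.467). In the other direction, 33 calls scored under 4. The lowest was LSU3 1344 at 1.11, beside LSU3 1343, followed by SSU 1054 at 1.52, beside SSU 1053. The deposited score does not cover SR1, SR2, SR4 and SR6, on which 15 positions were called.

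Counts were also high at the last listed positions of several rRNAs, where a full flank was lacking and no test was made. These positions were taken as near the 3′ ends, since the lengths of the reference sequences are not given in the sources used here. LSU5 1780 had 611 ± 35.4 counts (SD, n = 3), SR1 215 had 682 ± 41.4, SR6 73 had 583 ± 57.5, SR2 183 had 523 ± 34.5, SR4 134 had 342 ± 28.2 and 5.8S 170 had 333 ± 17.5. Each was within the last 2 listed positions of its rRNA. SSU differed: its last 20 positions, 2184 to 2203, had a mean of 1.02 counts, against 54.0 over the 20 positions before them.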

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

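The tests in this part were chosen after the result was seen. Signal outside the tested positions was found at the last listed positions, taken as near the 3′ end, of 6 rRNAs in all libraries. The median count per position in these rRNAs lay between 13.7 (5.8S) and 18.7 (SR1 and SR4). The mean was 611 counts at LSU5 1780, 332.7 at 5.8S 170, 681.7 at SR1 215, 523.3 at SR2 183, 342.0 at SR4 134 and 583.3 at SR6 73. Each position ranked within the top 5% of its rRNA, which was also the rule by which these peaks were picked.

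LSU3, with 48.7 counts at 1520, and SSU, with 3.33 at 2199, had no such peak. Reads stacking at the last listed position are argued against for LSU5, 5.8S, SR1 and SR4. These 4 peaks were followed by a further listed position, with at most a fraction of 0.0497 of the counts of its peak. Stacking just before the end of the reference sequence, whose length is not given, stays open for them. For SR2 183 and SR6 73, the last listed positions, any stacking stays open, and the position before lay at the 79.3rd percentile or higher. A terminal peak may come from the natural 3′ end of the molecule or from a 2′-O-methylated nucleotide there, and neither was tested, because the labels name no library without oxidation. No biological explanation was tested, since the design has a single group.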

How the results depend on the processing

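The 25 named sites were picked as the largest folds, above 4-fold in each library, so keeping a call under other settings was largely set by the selection. All 25 kept their direction and their call under the 17 other settings, but not their fold. With flanks of 12 positions 13 of them fell by over 1.5 times (LSU3 560 from a log2 fold of 5.98 to 2.56, LSU3 1384 from 8.41 to 5.36, SSU 2048 from 6.73 to 4.43). With flanks of 2 positions 8 rose and 2 fell by that much (SSU 1833 from 5.54 to 7.89), 5 rose with the flank median and 16 fell with pseudocount 5. The number of calls stayed within 1.5 times of 220 in DESeq2 (165), with TMM factors (220, with no change since the library term absorbs them), in limma (190 with pseudocount 1, 154 with pseudocount 5, 279 with the flank median), with flanks of 2 or 12 positions (223 and 212), without the count filter (221), with 50 counts at the site (216) and with no replicate block (220). Of the calls, 161 remained with flanks of 2 positions and 178 with flanks of 12. It moved with the fold threshold by construction: 586 at 2-fold, 103 at 8-fold, 58 at 16-fold (added after the data were seen) and 1297 with no threshold. Without one library it ranged from 199 to 219. The comparison of calls over rRNAs passed the threshold with flanks of 2 positions (Fisher's exact test, p = 0.00424), at 8-fold (0.0157) and at 16-fold (0.0398), and the cause was not tested. Adjacent calls fell to 0 with flanks of 2 positions (permutation p = 0.0003), where a neighbour weighs more in the flank than with 6, and ranged from 1 to 5 without one library. Without the 10 highest positions the 5.8S share of counts moved from 3.23% to 3.39%, by more than its SD over libraries. The other shares changed by less than their SD. LSU3 fell from 25.2% to 24.0% and the rest rose, such as SR1 from 3.36% to 3.53%. The lowest score taken was 6.48 for 205 positions, 14.5 for 100 and 37.7 for 50, with 139, 88 and 46 called; counting calls within 1 nt left 139. Spearman's rho between libraries, as ratios to the flanks, was 0.933 (LM1 and LM4), 0.926 (LM1 and LM5) and 0.918 (LM4 and LM5), and for positions with 50 counts 0.864 (LM1 and LM5) and 0.845 (LM4 and LM5). Beside calls, flanks of 2 positions gave -0.663, -0.767, -0.311 and -0.644 at offsets -2, -1, 1 and 2. The 8-fold threshold gave -0.425, -0.718, -0.777, 4.71, -0.146 and -0.467 at offsets -3 to 2; it takes 103 of the 220 calls, and flanks of 2 positions share 161 with them. Without one library these values ranged from -0.473 to -0.341 at offset -2, from -0.413 to -0.299 at -1, from 3.67 to 3.73 at the site, from -0.456 to -0.335 at 2 and from -0.544 to -0.492 at 3. The count minimum left 154 positions untested, and planted 6-fold sites, near the 4-fold null, were recovered in 44% of cases on the smooth simulated background. The comparisons of bases and motifs were not run for want of a sequence.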

Other observations

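All tests in this part were chosen after the result was seen. Only the shares of counts per rRNA and the medians at single offsets, repeated here from above, were planned descriptions. Some stretches of the rRNAs held almost no counted 3′ ends, and whether ends there could be counted was not tested. Runs of at least 10 positions with a mean of 4 or fewer counts were SSU 1329 to 1343 (mean 1.2), SSU 2184 to 2203 (1.0), LSU5 682 to 694 (0.79), LSU5 941 to 950 (0.70) and LSU3 550 to 559 (0.67), where the median was 15.7 counts in SSU, 16.3 in LSU5 and 13.3 in LSU3. The LSU3 run ends directly before the named site LSU3 560.

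The last 20 SSU positions held a fraction of 0.0188 of the mean count of the 20 before them, with 23, 28 and 10 counts in LM1, LM4 and LM5. A general loss of ends near rRNA 3′ termini is argued against as the whole cause: the median of the last 20 positions over that of the 20 before was 0.0165 in SSU and at least 0.312 in the other 7 rRNAs. It was below 1 in 5.8S (0.312), LSU5 (0.34), LSU3 (0.563) and SR1 (0.57), so a smaller loss there stays open. A reference sequence that runs past the end of the molecule cannot be told apart from other explanations: the highest of the 3 positions before the stretch (89.7 counts) lay at the 93.2nd percentile of SSU, below the level of the terminal peaks. The design gives no biological explanation to test.

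LM5 had a lower share of LSU5 counts, 0.883 of the mean of LM1 and LM4. A few dominant positions are argued against, as the ratio was 0.888 without the 10 highest LSU5 positions. Loss of a part of the molecule is argued against too: the 9 windows of 200 nt ranged from 0.817 to 0.908. A loss that grows with length would lower SSU, which spans more positions, at least as much, but its ratio was 0.986 (SD over windows 0.031). The rRNAs shorter than LSU5 all rose in LM5, with ratios of 1.1 (LSU3), 1.05 (5.8S), 1.14 (SR1), 1.16 (SR2), 1.17 (SR4) and 1.15 (SR6). Shares within a library depend on each other, and a loss related in part to length stays open. A difference in the amount of LSU5 RNA, in how it was recovered or in how its reads were counted stays open, and no biological explanation was tested because the labels give LM5 no condition of its own.

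LM5 also had the lowest count, scaled to library totals, at 19 of the 25 named sites, against 33.3% of the 959 other tested positions with a mean of at least 50 counts. The median log2 ratio of LM5 to the mean of LM1 and LM4 was -0.14 at the named sites and 0.039 at the others. The comparison was not matched for count, so it does not separate the named sites from high-count positions in general. For the calls as a whole another measure, the median log2 fold over flanks, was 3.05 in LM1, 3.02 in LM4 and 3.13 in LM5. Their share of the counts was 30.8% in LM1, 31.3% in LM4 and, lowest, 30.4% in LM5 (SD 0.48). Scaled counts were not compared site by site over all calls.

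The chi-square per position between LM1 and LM4 did not move in one direction with the count. It was 1.15 over the 2924 positions with a mean of 10 to 50 counts, 1.53 over 869 from 50 to 200, 2.56 over 69 from 200 to 400, 2.04 over 45 from 400 to 800 and 0.973 over the 13 with 800 or more. For LM1 and LM5 these values were 1.43, 2.49, 5.20, 7.26 and 2.73, and for LM4 and LM5 they were 1.47, 2.73, 5.43, 10.1 and 3.92.

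If strong sites collect ends from fragments around them, the positions between strong sites should hold fewer counts. Across 55 windows of 100 nt in SSU, LSU5 and LSU3, the number of positions with 400 or more counts correlated with the median count of the other positions at a Spearman's rho of -0.301 (permutation p = 0.0263; Pearson's r -0.293), a weak negative relation. Windows are stretches of the same molecules, not independent replicates. Within rRNAs the rho was -0.23 in SSU (22 windows), -0.399 in LSU5 (18) and -0.277 in LSU3 (15), not tested singly.

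Shortening from the 3′ side that stops at a protected nucleotide might be expected to deplete the positions just downstream of a site. At the 196 isolated calls, the median log2 ratio of counts 1 to 3 nt downstream to 1 to 3 nt upstream was 0.0068 (95% bootstrap interval -0.24 to 0.20), and downstream was lower at 97 of them (exact sign test, p = 0.943). The ratio pools offsets that went opposite ways: the median signal was higher downstream than upstream at 1 nt (-0.0073 and -0.32) and lower at 3 nt (-0.545 and -0.209). A depletion within the bootstrap interval cannot be excluded.

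Gathering of the calls in some stretches of an rRNA was not detected. A high position raises the flank means around it, which works against calls nearby. Random placement is therefore not the value for unrelated sites here either. Over windows of 100 nt in SSU, LSU5 and LSU3, the lowest adjusted permutation p was 0.684 for the 4-fold calls with flanks of 6 positions, which does not show that the calls are evenly spread. It was 0.297 at 8-fold (LSU5), 0.278 at 16-fold (LSU3) and 0.327 with flanks of 2 positions (SSU and LSU3). The densest windows were picked for their calls, while the expected number is that of a given window and not of the highest of many. They were SSU 2001 to 2100 with 7 calls (3.23 expected), LSU5 901 to 1000 with 7 (3.04) and LSU3 501 to 600 with 7 (4.77). At 16-fold this LSU3 window had 6 where 1.70 were expected.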
